A study of Mus musculus with 17 samples.

How the data were processed

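Bulk poly-A RNA-seq was available for 17 mouse libraries, 10 DDLPS, 3 WDLPS and 4 Normal Fat, grouped as the labels give them. Per the labels' protocols, RNA was extracted with a column kit from frozen tissue of about 30 mg, and libraries were made at 2 sites. The labels give no site per library, so the title series (13 AS and 4 R titles) stands for where a library was made. The names under which counts were deposited place the AS libraries with a UM core and the R libraries with Novogene.

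The authors deposited raw whole-number counts per Ensembl gene in 3 tables, of which 1 combines the other 2. The 3 tables held 0 differing values for the 17 libraries. The submitters' processing notes name fastp, HISAT2 2.05, featureCounts 1.5.0-p3 and the mouse build GRCm39, without giving their order or settings. The counting is not stated to use strand, so reads of overlapping and antisense genes cannot be told apart, and near-identical gene copies share reads. The tables hold 55491 entries, of which 55487 are mouse genes and 4 are reporter or transgene sequences, which took at most 0.000329% of the counts of a library. A further 7 sample columns match no labelled sample and were not used here. Gene symbols were taken from the deposited tables, where 114 symbols are shared by several gene IDs. No coordinates are given, since the reference at hand was of another build.

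Total counts ran from 16223845 to 45676465 per library. A count of 0 was given a limit of 3 counts per library, covering counting error only. Genes were kept by edgeR's filterByExpr on the 3 groups, which left 18821. CPM values used TMM-scaled library sizes, and log2 CPM a prior count of 2.

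Each comparison was taken from 1 edgeR quasi-likelihood fit of all 17 libraries (edgeR 4.0.16 in R 4.3.3, 13 residual degrees of freedom, prior degrees of freedom 2.91, common dispersion 0.746) with group and title series as terms, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors come from the same fit. The model shares 1 estimate of the spread between groups. Adjusted p-values over the list alone were computed by Benjamini-Hochberg over the tested members of a list, or over 7 genes named in advance (Trp53, Mdm2, Cdk4, Hmga2, Cdkn1a, Cdkn2a and 1 that is not reported here). R titles hold no Normal Fat library, so the AS libraries were also fitted alone.

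The 37 gene lists comprised 22 cell type lists and 15 pathway or tissue quality lists. The first were adipocyte, brown and beige adipocyte, adipose progenitor and fibroblast, smooth muscle and pericyte, endothelial, lymphatic endothelial, T cell, regulatory T cell, cytotoxic and NK cell, B cell, plasma cell, macrophage, monocyte and neutrophil, dendritic cell, mast cell, lymph node stroma and high endothelial venule, skeletal muscle, mammary epithelium, skin, nerve, erythroid, and bone and cartilage. The second were p53 targets, FOXO targets repressed by PI3K-AKT signalling, orthologs of the human liposarcoma amplicon, lipogenesis, oxidative phosphorylation, cell division, hypoxia and glycolysis, collagen and matrix, proteases and inhibitors, checkpoints, MHC class I, MHC class II, interferon response, cytokines, and the immediate early response. Of the list genes 4 were not named in the tables, and 1 hypoxia gene, Aldoa, had a pair of IDs, giving 21 tested members for 20 names. Lists share some genes, and several of their genes are expressed by more than 1 cell type. Lists were tested with camera at a preset correlation of 0.01 (limma 3.58.1), with Benjamini-Hochberg adjustment over the 37 lists of a comparison. Camera with an estimated correlation and fry were alternatives. A list score is the mean log2 CPM of its members in a library.

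The genes named in the text were the 7 genes above, for each comparison up to 8 genes per direction with the largest change among those past the threshold, with a mean log2 CPM of at least 3 and no predicted symbols, and up to 4 members of each list with the smallest p, whether or not they passed. Other genes are named as chosen after their values were seen. The groups, comparisons, tests, lists, naming rule and the settings listed next were set before the data were examined, except where stated.

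The edgeR test was tested on simulated counts of 18821 genes with 200 genes changed, drawn with the fitted dispersions. Between DDLPS and Normal Fat it recovered 0% of genes changed by 1 log2, 20.9% by 2 and 62.1% by 4, with 2 false calls, where DESeq2 recovered 8.96%, 50.7% and 75.8% with 76 false calls. Between WDLPS and Normal Fat edgeR recovered 0%, 5.97% and 50.0% with 0 false calls, and DESeq2 4.48%, 23.9% and 81.8% with 76. Between DDLPS and WDLPS edgeR recovered 0%, 28.4% and 59.1% with 1 false call, and DESeq2 8.96%, 55.2% and 83.3% with 111. With dispersions lowered below the fitted ones, edgeR recovered 17.9%, 62.7% and 89.4% between DDLPS and Normal Fat, with 10 false calls.

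Other settings tried were RLE and upper-quartile normalization, no filter on low counts, a stricter filter, a fit without title series, the AS libraries alone, only the 2 groups compared, DESeq2 1.42.0, a test against a fold change of 2, the 2 list tests above, list scores as medians, and leaving out each library in turn. Settings chosen after the data were seen were an adjusted p under 0.1, robust dispersions, limma-voom with quality weights, the fit without DDLPS 3 and WDLPS 3, without 4 muscle-rich libraries, without 5 libraries with reads of Glycam1 and Chst4, and with B cell and skeletal muscle scores as covariates.

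Immune list scores were summarised within groups by SD and range. Correlations of the T cell score with 9 other list scores among DDLPS tumors were planned over all 10. They were computed only within the 8 tumors of the larger cluster, with two-sided exact permutation tests over 40320 pairings, and not within the 5 AS tumors of it, which are too few. Genes in both lists were left out of the second. Other splits of the libraries were drawn with a fixed seed, 60 for edgeR and 40 for DESeq2 (all 35 for WDLPS and Normal Fat). Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for scores, correlations and plots.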

Results

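Bulk poly-A RNA sequencing measured gene expression in 17 tissue pieces from a mouse model of liposarcoma, a cancer of fat tissue. In this model AAV8-Cre, a viral vector carrying the recombinase Cre, was injected into the flank fat pad of mice with floxed alleles, among them those of the tumor suppressor gene Trp53. The libraries comprised 10 dedifferentiated liposarcomas (DDLPS), 3 well-differentiated liposarcomas (WDLPS) and 4 fat pads of uninjected mice (Normal Fat). Total counts per library ranged from 16223845 in DDLPS 9 to 45676465 in DDLPS 1, and 18821 genes were tested. The titles form 2 series, AS with 7 DDLPS, 2 WDLPS and 4 Normal Fat libraries, and R with 3 DDLPS and 1 WDLPS. Every library was labelled as a separate sample, so the p-values measure the spread between these samples. Expression is given in CPM (counts scaled to normalised library size) as mean ± SD, with n = 10 DDLPS, n = 3 WDLPS and n = 4 Normal Fat throughout. Limits from a count of 0 cover counting error only.

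The pieces differed in tissue content within every group. Lymphocyte genes were high in Normal Fat 1, Normal Fat 4, DDLPS 2 and DDLPS 3, whose mean log2 CPM over the T cell list was 6.91, 5.53, 5.43 and 6.96. WDLPS 1 held 2.67 on that scale, and its B cell genes summed to 3588 CPM. Reads of both Glycam1 and Chst4, genes of the high endothelial venules through which lymphocytes enter lymph nodes, were present in those 5 libraries and absent from the other 12. Glycam1 is also a milk protein gene, and mammary epithelium genes averaged 6.56 in Normal Fat 2, 6.78 in Normal Fat 4, 6.94 in WDLPS 1 and 6.80 in DDLPS 3. Skeletal muscle genes averaged 13.09 in DDLPS 1, 10.22 in Normal Fat 3, 8.89 in DDLPS 8 and 7.47 in WDLPS 3. Fat cell genes averaged 8.42 to 10.71 in Normal Fat, and 8.42 in DDLPS 3, 8.82 in DDLPS 8 and 5.69 in DDLPS 1 against at most 2.55 in the other 7 DDLPS tumors. The library labelled DDLPS 3 had a mean Spearman correlation of 0.910 with Normal Fat and 0.811 with the other DDLPS. WDLPS 3 had 0 counts for 5334 of the tested genes, against 320 to 3504 in the other libraries.

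**Figure D1:**
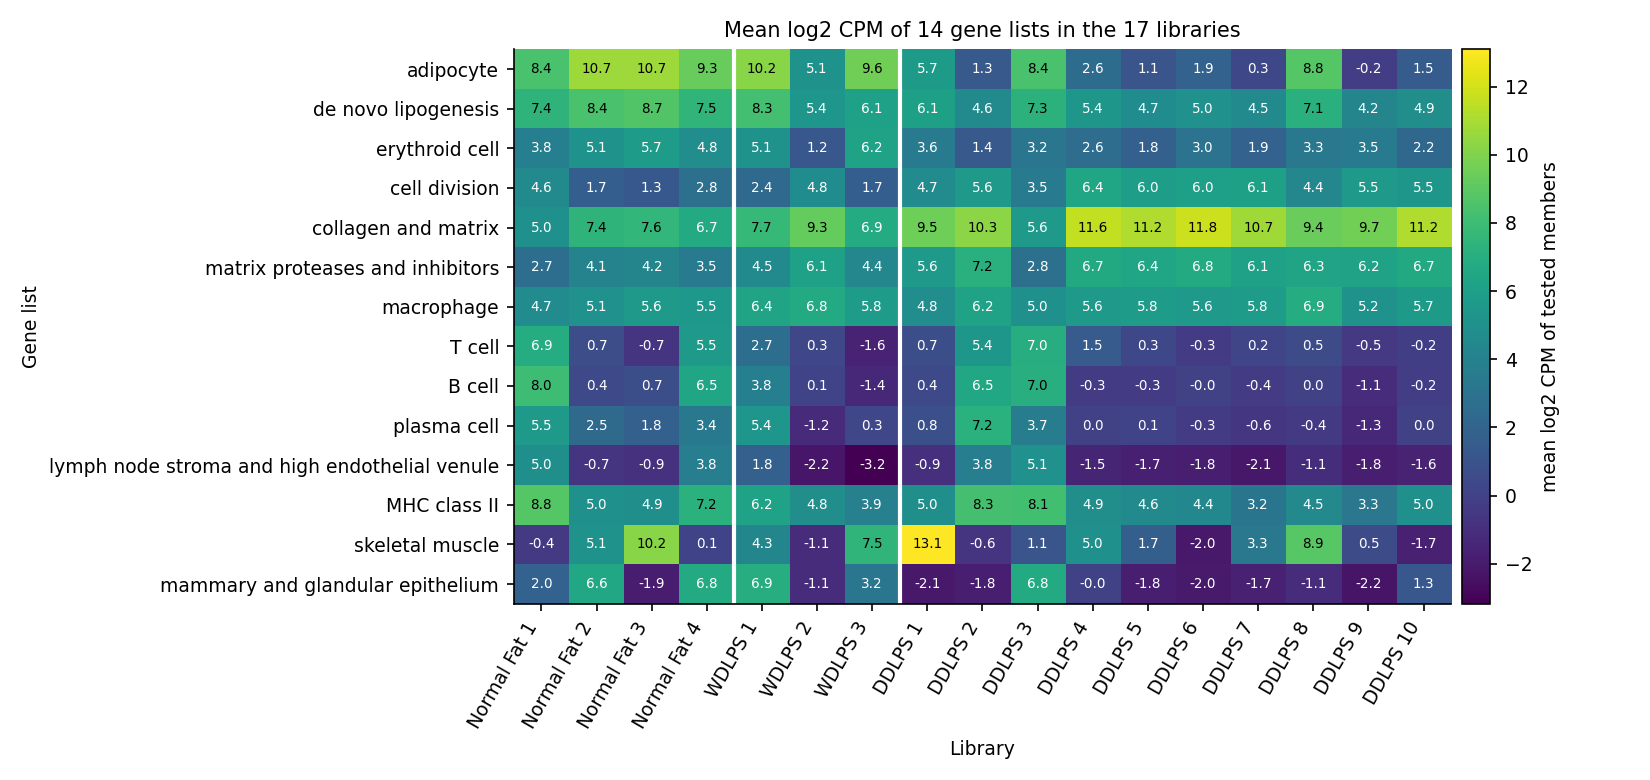
Mean log2 CPM of 14 gene lists (vertical axis) in each of the 17 libraries (horizontal axis, grouped as Normal Fat, WDLPS and DDLPS). Lighter color stands for higher values. T cell genes were high in Normal Fat 1 and 4 and DDLPS 2 and 3, and skeletal muscle genes reached 13.09 in DDLPS 1.

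Trp53 was examined first, since Cre deletes its floxed part while counts over a whole gene include exons outside that part. Genes named in advance were tested with edgeR and adjusted over a list of 7 alone by the Benjamini-Hochberg method. Trp53 (ENSMUSG00000059552), the p53 gene, had 31.3 ± 24.2 CPM in DDLPS, 19.3 ± 9.80 in WDLPS and 60.8 ± 40.1 in Normal Fat. Its log2 differences of -0.79 (SE 0.51) and -1.46 (SE 0.69) did not pass, with adjusted p-values over the 7 genes of 0.193 and 0.0897, and 0.0275 and 0.0396 without DDLPS 3, which had 89.2 CPM. Trp53 was high where lymphocyte genes were, at 116 CPM in Normal Fat 1, 63.0 in Normal Fat 4 and 60.5 in DDLPS 2, against 38.1 in Normal Fat 2 and 25.8 in Normal Fat 3. Without the 5 libraries with Glycam1 and Chst4 reads the adjusted p-values over the 7 genes were 0.0740 in DDLPS and 0.0242 in WDLPS, and with B cell and skeletal muscle scores as covariates 0.232 and 0.0333. The fit without those 5 libraries held only WDLPS 2 and 3 and Normal Fat 2 and 3 of the WDLPS and Normal Fat groups.

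Cdkn2a (ENSMUSG00000044303), which encodes the cell cycle inhibitor p16 and the p53 activator p19, was scarce in uninjected fat and abundant in both tumor types. It had 284 ± 139 CPM in DDLPS, 204 ± 212 in WDLPS and 1.01 ± 1.24 in Normal Fat. Every tumor lay above every Normal Fat library, the lowest tumor being DDLPS 3 at 6.89 CPM and the highest Normal Fat library 2.77 CPM. Cdkn2a rose by 8.17 log2 (SE 1.35) in DDLPS and 7.68 (SE 1.37) in WDLPS, with edgeR adjusted p-values over the list alone of 0.00012 and 0.000272 and over all genes of 0.0548 and 0.452. Its calls over the 7 genes stood without any 1 of the 17 libraries. Cdk4 (ENSMUSG00000006728), a cell cycle kinase amplified in human liposarcoma, had 203 ± 89.1 CPM in DDLPS, 158 ± 67.7 in WDLPS and 78.4 ± 18.8 in Normal Fat. It rose in DDLPS by 1.37 (SE 0.39, adjusted p over the list alone 0.00657, over all genes 0.0747) with no overlap of libraries. In WDLPS its difference of 1.01 (SE 0.47) had an adjusted p over the 7 genes of 0.0897, and 0.0350 without WDLPS 1. Without the 5 libraries with Glycam1 and Chst4 reads, which include WDLPS 1, the difference was 1.79 (adjusted p over the 7 genes 0.0205). That fit held only WDLPS 2 and 3 against Normal Fat 2 and 3.

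Hmga2 (ENSMUSG00000056758), a chromatin protein gene of the same human amplified region, had 63.5 ± 92.8 CPM in DDLPS, from 0.0281 in DDLPS 3 to 243 in DDLPS 7. It had no read in any WDLPS library, and 1 and 2 reads in Normal Fat 1 and 4. Adjusted over the list alone with edgeR it was higher in DDLPS than in Normal Fat (adjusted p = 0.00468, over all genes 0.0671). Against WDLPS its DDLPS mean was at least 486-fold higher, taking 3 counts per library as the limit (adjusted p over the list alone 0.0193, over all genes 0.128). That fold does not hold for each tumor, since DDLPS 3 had 1 read and DDLPS 8 had 3, no more than that limit. The call against WDLPS over the 7 genes ended without WDLPS 1, 2 or 3, at adjusted p-values of 0.0717, 0.0715 and 0.0737. It also ended with only the 2 groups fitted (0.0512) and without the 4 muscle-rich libraries (0.0651). The same held without the 5 libraries with Glycam1 and Chst4 reads (0.0713) and by limma-voom (0.281). Mdm2 (ENSMUSG00000020184), which targets p53 for degradation and is amplified in the human tumors, had 48.1 ± 23.5 CPM in DDLPS, 48.3 ± 19.9 in WDLPS and 42.8 ± 2.76 in Normal Fat. The p53 target Cdkn1a (ENSMUSG00000023067) had 52.3 ± 21.4, 76.2 ± 33.1 and 56.2 ± 30.2 CPM. Neither passed in any comparison. Between DDLPS and WDLPS, Trp53, Cdk4 and Cdkn2a did not pass over the 7 genes either, with adjusted p-values of 0.465, 0.537 and 0.725.

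**Figure D2:**
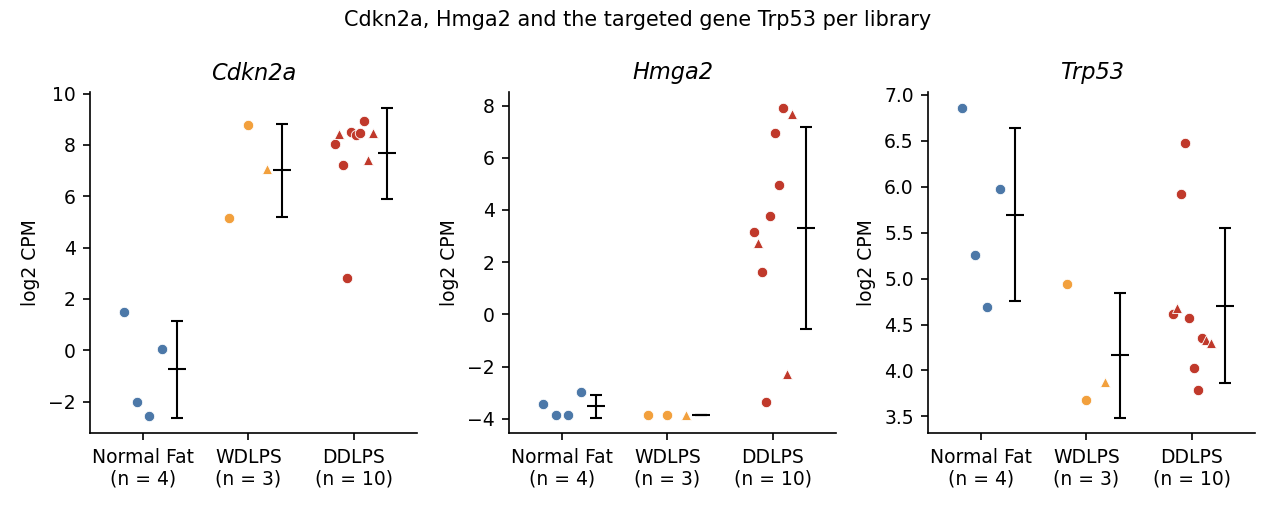
Log2 CPM (vertical axis) of Cdkn2a, Hmga2 and Trp53 in each library of the 3 groups (horizontal axis), with circles for AS titles, triangles for R titles and a bar for the mean ± SD. All 13 tumors lie above all 4 Normal Fat libraries for Cdkn2a, with DDLPS 3 the lowest tumor.

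The first comparison asked how DDLPS tumors differ from uninjected fat. DDLPS held more transcript of matrix, protease and cell division genes and less of fat cell genes. The matrix glycoprotein Tnc had 2647 ± 2692 CPM against 12.6 ± 5.22 in Normal Fat, and the proteoglycan Bgn 3242 ± 2070 against 188 ± 40.4. The fibril-associated collagen Col12a1 had 779.8 ± 879 CPM against 11.9 ± 3.80, and Col11a1, a fibrillar collagen of cartilage, 156 ± 258 against 1.27 ± 1.04. Adjusted over the list alone with edgeR, 19 of 22 collagen and matrix genes rose, at a list median of 3.78 log2, and 16 to 21 rose with any 1 library left out. The median of all tested genes was 0.06. The protease inhibitor Timp1 rose from 2.10 ± 1.41 to 146 ± 87.6 CPM with no overlap of libraries, and the collagenase Mmp13 from 0.821 ± 0.801 to 48.8 ± 86.3. With Mmp10 and Mmp14 they were among the 10 of 16 protease and inhibitor genes that rose over the list alone, at a median of 2.82 and unchanged in number without any 1 library. DDLPS 3 lay apart from the other DDLPS, at a mean log2 CPM of 5.62 for matrix genes and 2.80 for proteases.

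Genes of DNA synthesis and mitosis were higher in DDLPS. Tyms, which makes thymidylate for DNA synthesis, had 43.2 ± 21.9 CPM against 7.65 ± 2.52 in Normal Fat. The mitotic kinase Aurka had 30.7 ± 17.7 against 5.79 ± 3.44, the mitotic ubiquitin carrier Ube2c 46.9 ± 18.1 against 8.46 ± 4.87, and the S phase regulator E2f1 29.2 ± 10.5 against 8.93 ± 1.47. Over the list alone 25 of 28 cell division genes rose, at a median of 2.58. The number was 16 without Normal Fat 2 or 3 and 15 without Normal Fat 4, and the lymphocyte-rich Normal Fat 1 had the highest cell division score of its group, 4.63. For hypoxia and glycolysis, 7 of 21 genes rose over the list alone, among them the glucose transporter Slc2a1 (120.2 ± 81.6 against 30.3 ± 9.90 CPM), Pgk1, Egln3 and Pkm, while the mitophagy gene Bnip3, chosen after its values were seen, fell. No gene of that list passed without DDLPS 5, DDLPS 7 or Normal Fat 1, 2 or 4, and 3 did without DDLPS 4 or Normal Fat 3. Without the 4 muscle-rich libraries 5 passed, and with the B cell and skeletal muscle covariates 4.

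Fat cell genes were lower in DDLPS. Pparg, the master regulator of fat cell differentiation, had 13.4 ± 21.0 CPM against 151 ± 109.7 in Normal Fat, and its partner Cebpa 95.4 ± 136 against 699.6 ± 449.8. Adrb3, the fat cell adrenergic receptor, had 7.14 ± 18.3 against 205 ± 99.4, with no overlap of libraries. Over the list alone 12 of 22 adipocyte genes fell, including Pnpla2, at a list median of -3.95. The number was 2 without DDLPS 2, 4, 5, 6 or 7 or Normal Fat 2 or 3, 5 without Normal Fat 4 or WDLPS 3, 7 without DDLPS 1 or WDLPS 2, and 19 without DDLPS 3. It was 2 without the 4 muscle-rich libraries, 6 with only the 2 groups fitted, and 21 with B cell and skeletal muscle scores as covariates. Of the fatty acid synthesis enzymes, Scd1 had 614 ± 999 CPM against 16214 ± 13558 and Fasn 318 ± 264 against 2349 ± 1249.5. They fell over the list alone with Slc25a1, Srebf1 and Acaca, the last named after its values were seen, as 5 of 12 lipogenesis genes at a median of -1.60, and 2 passed without Normal Fat 3. The beige fat regulator Ebf2 fell over its list of 12 genes (7.13 ± 14.1 against 27.5 ± 19.9 CPM), a call that ended without DDLPS 4, without Normal Fat 3, in the fit without title series and without the 5 libraries with Glycam1 and Chst4 reads, and 5 genes passed without DDLPS 1. Among progenitor and fibroblast genes, the stem cell marker Pi16, Gsn and Col15a1 fell and the growth factor receptor Pdgfrb rose over the list alone, at a list median of 0.40 and mean of -0.47. The number was 7 without DDLPS 3, 1 without Normal Fat 2, 0 without Normal Fat 3 and 2 without the 5 libraries with Glycam1 and Chst4 reads.

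Macrophage genes passed on both sides, while the monocyte and cytokine genes that passed in the full set were all higher in DDLPS. The scavenger receptor Msr1 had 41.6 ± 22.2 CPM against 6.33 ± 2.66 in Normal Fat, the lipid receptor Trem2 29.0 ± 16.5 against 3.58 ± 2.21, and the resident macrophage gene Cd163 8.62 ± 12.6 against 49.8 ± 37.0. Over the list alone 9 of 22 macrophage genes rose and 2 fell, with a median of 0.73. The number was 3 without DDLPS 2, DDLPS 5 or Normal Fat 4, 4 without DDLPS 7, 5 without Normal Fat 1 and 0 without Normal Fat 2, and it was 3 without the 5 libraries with Glycam1 and Chst4 reads and 2 with B cell and skeletal muscle scores as covariates. The monocyte attractants Ccl2 (99.0 ± 104 against 4.08 ± 1.14 CPM) and Ccl7 (68.2 ± 43.1 against 3.63 ± 0.298), the cytokine Il1b and the neutrophil attractant Cxcl1 were among 8 of 28 cytokine genes that rose over the list alone, at a median of 1.73. That number was 5 without DDLPS 2, 5 or 10 or Normal Fat 2 or 3, and 4 without Normal Fat 4, 0 without the 4 muscle-rich libraries and 13 with only the 2 groups fitted. Over the monocyte and neutrophil list 6 of 17 genes rose, including Il1b and Vcan, which the cytokine and matrix lists also hold, and Mmp8 and Chil3, at a median of 1.38. It was 3 without Normal Fat 2 and 2 without Normal Fat 4. The checkpoint ligand Cd276 rose from 7.69 ± 4.20 to 137 ± 91.8 CPM as the 1 of 23 checkpoint genes to pass over its list, and a further gene passed without Normal Fat 1. Without the 4 muscle-rich libraries 0 genes of that list passed, and without the 5 libraries with Glycam1 and Chst4 reads 4. With the covariates the checkpoint list passed camera as higher (median 0.63, adjusted p = 0.0201), where it had a median of -0.21 and did not pass in the full set.

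No T cell, regulatory T cell, cytotoxic and NK cell, B cell, dendritic cell, MHC class I, MHC class II or interferon gene passed over its list alone with edgeR. With 1 library left out, 1 gene passed among B cell genes (without WDLPS 3), dendritic cell genes (without Normal Fat 1 or DDLPS 2) and MHC class I genes (without DDLPS 1 or 3). Their list medians in DDLPS against Normal Fat were -0.71, -0.48, -0.66, -1.37, -0.12, -0.45, -0.44 and 0.29, in the setting of Normal Fat 1 and 4 being rich in lymphocyte genes. With B cell and skeletal muscle scores as covariates the T cell median was 0.83, on the higher side by camera (adjusted p = 0.0201), so no direction is drawn for T cell genes. Lck, a T cell kinase, had 33.1 ± 75.5 CPM in DDLPS and 84.6 ± 117 in Normal Fat, and the B cell receptor Fcer2a 14.1 ± 32.8 and 87.6 ± 129.9. Lymph node stroma genes had a median of -0.76, endothelial genes -0.38, smooth muscle and pericyte genes -0.07, skeletal muscle genes 1.40 and mast cell genes -2.27, with no gene past its list. Nor did any mammary (-1.85), skin (-1.91), nerve (-1.41), FOXO target (-0.47) or oxidative phosphorylation gene (-0.37) pass. Without DDLPS 3, whose mammary genes were high, 13 mammary, 8 skin and 7 nerve genes were lower over the list alone, and without the muscle-rich DDLPS 1 16 skeletal muscle genes were lower. Of these lists and the FOXO and endothelial lists, 1 or 2 genes passed without WDLPS 1 (FOXO, endothelial, mammary), WDLPS 2 (mammary), WDLPS 3 (FOXO, endothelial, mammary, skin), DDLPS 3 (FOXO), DDLPS 8 (endothelial, skin), DDLPS 9 (mast cell) or Normal Fat 2 (skin). Hemoglobin genes were lower, Hba-a2 having 86.3 ± 60.5 CPM against 451 ± 248, and 5 of 7 erythroid genes fell over the list alone (Hba-a1, Hba-a2, Alas2, Hbb-bt and Hbb-bs, the last named after its values were seen), at a median of -2.57. Near-identical hemoglobin copies make the split of reads between them uncertain.

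In the remaining lists the immediate early gene Fosl1 (31.7 ± 30.0 against 0.0147 ± 0.0174 CPM) and Ier3 rose over the list alone, at a list median of 0.17, with 1 gene passing without the 4 muscle-rich libraries or with the B cell and skeletal muscle covariates. The skeletal regulator Runx2 (33.7 ± 21.2 against 10.3 ± 3.63 CPM), Ctsk and the cartilage proteoglycan Acan, which had no read in Normal Fat, rose over the bone and cartilage list, at a median of 0.81 that did not change with Acan put at its limit. Without Normal Fat 2 or 4, or with the B cell and skeletal muscle covariates, 1 gene of that list passed. Over the p53 target list Ckap2 and Gtse1, which also act in mitosis, rose and Dcxr fell, at a median of -0.00. That number was 6 without DDLPS 1 and 0 without Normal Fat 2, 3 or 4, without the 4 muscle-rich libraries or with the B cell and skeletal muscle covariates, and 6 without the 5 libraries with Glycam1 and Chst4 reads. Hmga2 and Cdk4 passed over the list of human amplicon orthologs, at a median of 0.14, where 4 genes passed without DDLPS 3, 1 without the 4 muscle-rich libraries, and 0 without Normal Fat 2 or 3 or with the covariates. Prdm1 and Sdc1, which plasma cells share with other cell types, rose over the plasma cell list at a median of 0.17, and 5 genes passed without DDLPS 2, 8 without the 5 libraries with Glycam1 and Chst4 reads, 1 without Normal Fat 4, and 0 without Normal Fat 2 or 3 or without the 4 muscle-rich libraries. Pdpn passed over the lymphatic list (median 0.35), where 0 genes passed without DDLPS 4 to 10, WDLPS 3 or any Normal Fat library, so no direction is drawn.

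The camera test, which compares a list with all other genes at a preset correlation of 0.01, placed 17 of 37 lists past the threshold in DDLPS against Normal Fat. The 7 higher lists were cell division (adjusted p = 5.99e-21), collagen and matrix (4.13e-15), proteases (1.84e-06), cytokines (0.000596), monocyte and neutrophil (0.00169), hypoxia (0.00542) and macrophage (0.0266). The 10 lower lists were adipocyte (2.69e-19), erythroid (1.96e-07), lipogenesis (8.18e-06), nerve (0.000463), mast cell (0.000596), mammary (0.00213), skin (0.00256), B cell (0.0204), FOXO targets (0.0216) and oxidative phosphorylation (0.0312). None held with an estimated correlation, the smallest being adjusted p = 0.232 with an estimated correlation, for 8 of the 17 lists. The fry test, whose directional p asks whether a list's genes move on balance one way and whose mixed p asks whether they change in either direction, neither set against other genes, passed 9 and 14 lists. Camera put the skeletal muscle, plasma cell, progenitor, and brown and beige fat lists on the lower side although their medians were 1.40, 0.17, 0.40 and 0.19, and their means 1.53, 0.45, -0.47 and 0.01. The checkpoint, smooth muscle and p53 target lists, also on the lower side, had means of 0.07, 0.00 and 0.11.

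Over all genes edgeR with Benjamini-Hochberg adjustment called 1 gene, Klhl2 (ENSMUSG00000031605), an adaptor for protein ubiquitination. It had 23.6 ± 5.87 CPM in DDLPS and 124 ± 55.6 in Normal Fat with no overlap, a fall of 2.39 log2 (SE 0.31, adjusted p = 0.0155). That call ended without DDLPS 2, 4, 5 or 6 or Normal Fat 2 or 3, with adjusted p-values of 0.00404 to 0.167 over the 17 removals. At an unadjusted p under 0.05 there were 3934 genes, 2511 higher and 1423 lower, and DESeq2 called 2429. The libraries of the groups did not overlap for 427 genes, 2.27% of those tested against 0.2% by chance. The edgeR count was 2151 without DDLPS 3, 499 without DDLPS 8, 355 without Normal Fat 1, 281 without WDLPS 1, 2 without DDLPS 1 or WDLPS 2, and 0 without DDLPS 2, 4, 5 or 6 or Normal Fat 2 or 3. Within the AS libraries edgeR called 0 genes over all, and over the lists alone 16 matrix, 10 protease, 26 cell division, 10 adipocyte, 5 lipogenesis, 12 macrophage, 11 cytokine and 6 erythroid genes passed.

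**Figure D3:**
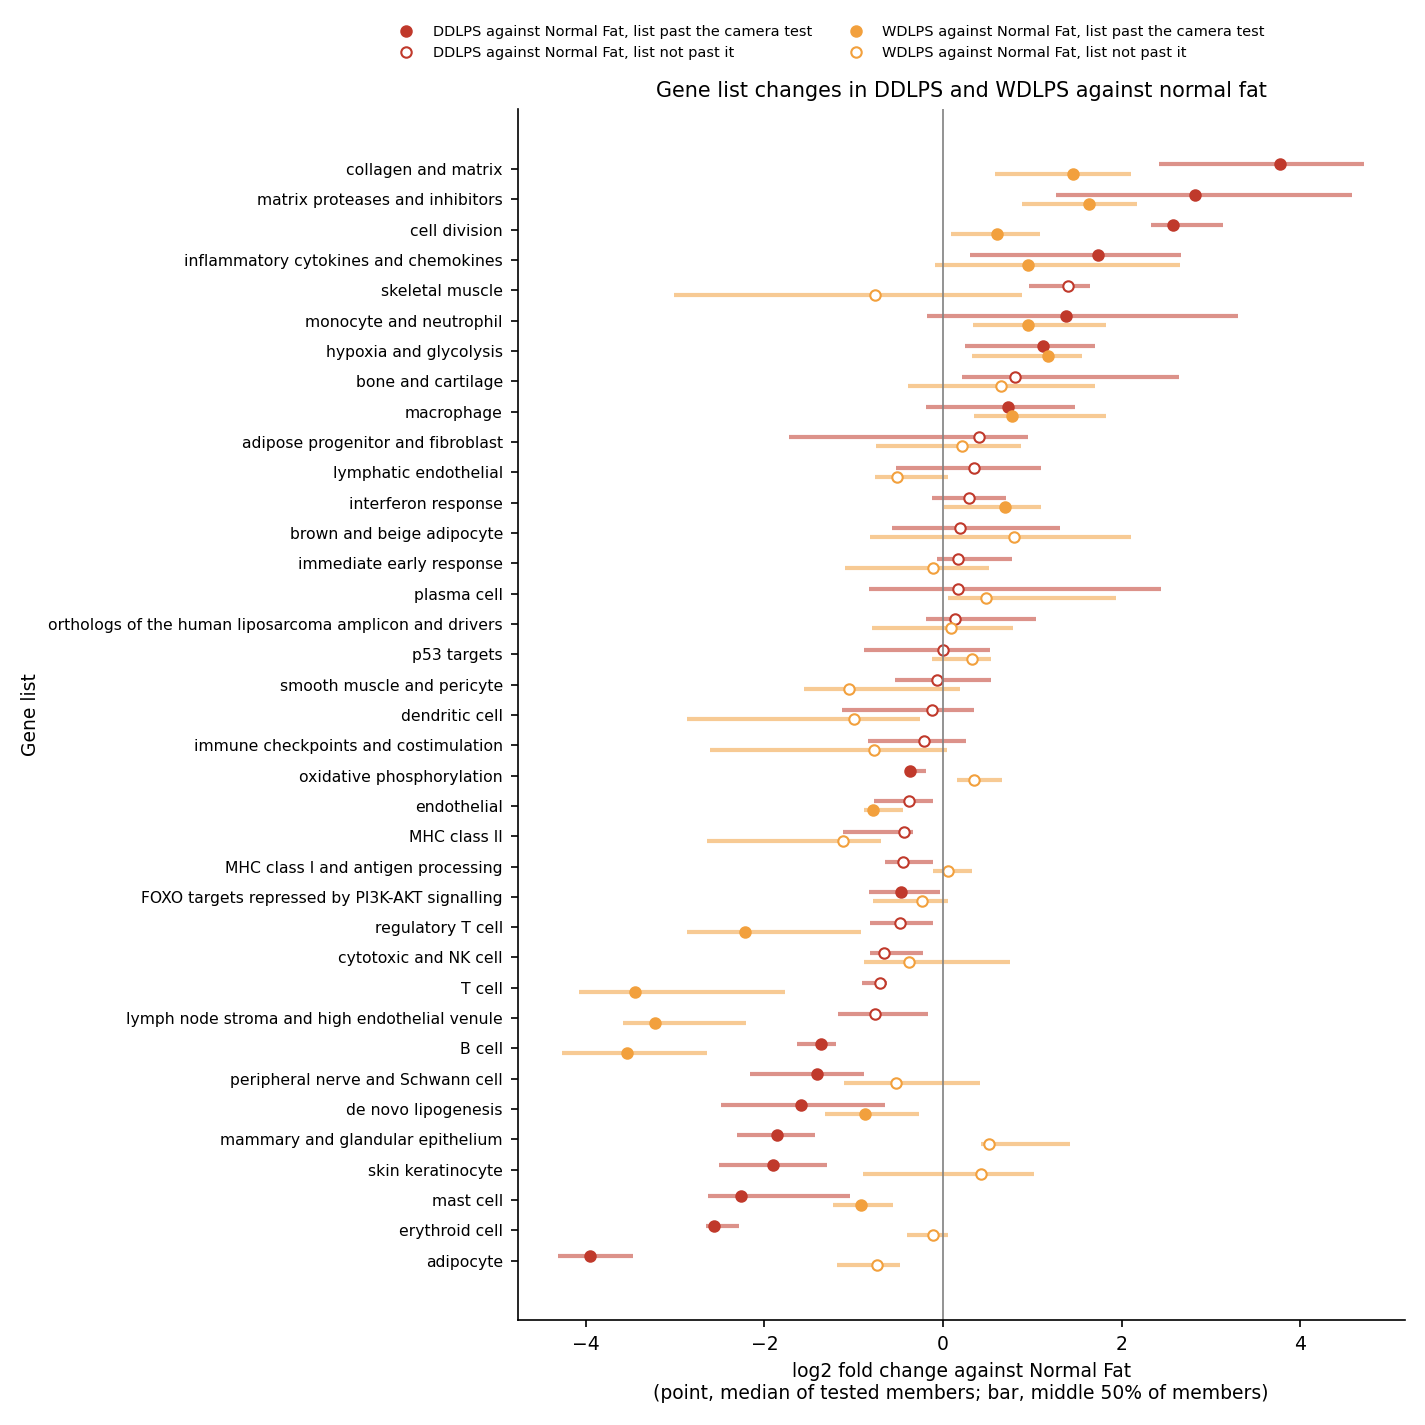
Median log2 fold change of each of the 37 gene lists (horizontal axis, log2) in DDLPS and WDLPS against Normal Fat, with a bar for the middle 50% of members and filled points for lists past the camera threshold at the preset correlation. Matrix genes sit at 3.78 in DDLPS and 1.46 in WDLPS, and adipocyte genes at -3.95 and -0.74.

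The second comparison asked how WDLPS tumors, which by name resemble mature fat, differ from uninjected fat. A minority of macrophage and chemokine genes were higher in WDLPS, in numbers that depended on the libraries and the fit. Trem2 had 124 ± 102 CPM against 3.58 ± 2.21 in Normal Fat, the antibody receptor Fcgr1 73.9 ± 51.9 against 7.99 ± 4.22, and the complement gene C1qb 477 ± 196 against 130.4 ± 54.9, each with no overlap of libraries. They rose over the list alone with C1qc, Msr1 and C1qa, as 6 of 22 macrophage genes at a median of 0.77, and 1 passed without Normal Fat 1 or 2 and 0 without WDLPS 2. The monocyte attractants Ccl7 (185 ± 175 against 3.63 ± 0.298 CPM), Ccl8 (327 ± 144 against 32.9 ± 26.6) and Ccl2 (94.6 ± 100.5 against 4.08 ± 1.14), with Ccl3 and Ccl4, the last named after its values were seen, rose as 5 of 28 cytokine genes over the list alone, at a median of 0.95. The number was 0 without WDLPS 2, 8 without DDLPS 8, 3 without DDLPS 3, and 2 without DDLPS 1, 4, 5, 7, 9 or 10, WDLPS 3 or Normal Fat 2, 3 or 4. Clec4d, Chil3 and Retnlg rose over the 17 monocyte and neutrophil genes (median 0.95), with 5 genes passing without WDLPS 1 and 0 without WDLPS 2. Within the AS libraries 5 macrophage, 5 cytokine and 4 monocyte and neutrophil genes passed over the list alone. With only the 2 groups fitted the numbers were 0, 2 and 0, without the 4 muscle-rich libraries 5, 1 and 1, and with the B cell and skeletal muscle covariates 1, 8 and 3.

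Few genes of other lists passed in WDLPS. Timp1, at 68.6 ± 58.7 CPM against 2.10 ± 1.41 with no overlap, rose over the 16 proteases (median 1.64), with 0 genes passing without WDLPS 2, 2 without WDLPS 1 and 3 without WDLPS 3, 3 without the 4 muscle-rich libraries, and 4 with only the 2 groups fitted. The oxygen sensor Egln3 passed over the hypoxia list (251 ± 328 against 6.65 ± 3.83 CPM, list median 1.18), with 0 passing without WDLPS 2, 5 without WDLPS 1, 4 without DDLPS 3 and 2 without Normal Fat 3 or WDLPS 3. It was 0 with only the 2 groups fitted and with the B cell and skeletal muscle covariates, and 5 without the 5 libraries with Glycam1 and Chst4 reads. Dio2 passed over the brown and beige fat list (median 0.80), where 2 genes passed without WDLPS 1 and 0 without WDLPS 2 or Normal Fat 1, 2, 3 or 4. Fosl1 and Egr3 passed over the immediate early list (median -0.11), where the count was 2 without DDLPS 1, 8 or 10, 3 without WDLPS 1, 1 without DDLPS 3 or WDLPS 3, and 0 otherwise. No direction is drawn from Egln3 or those 3 genes. No fat cell gene passed, Pparg having 102 ± 81.0 CPM against 151 ± 109.7 and Adrb3 31.3 ± 37.9 against 205 ± 99.4, at an adipocyte median of -0.74. No matrix gene passed, the matricellular gene Postn having 4738 ± 6887 CPM against 177 ± 152 with no overlap, at a list median of 1.46, and no cell division gene, at 0.60. T cell, B cell and lymph node stroma medians were -3.45, -3.54 and -3.23 with 0 genes past their lists, where Normal Fat 1 and 4 held the lymphocyte genes. Without WDLPS 1, 10 endothelial, 5 smooth muscle and pericyte, 5 lymphatic, 4 lipogenesis, 2 amplicon and 2 progenitor genes passed over the list alone, and 1 each of the matrix, FOXO, mast cell, checkpoint, erythroid and bone lists. Without DDLPS 3, 1 matrix, 1 progenitor, 1 lymphatic and 1 checkpoint gene passed, without WDLPS 3, 1 matrix and 1 lymphatic gene, without DDLPS 8, 2 progenitor genes, and without DDLPS 1 or 7, 1 lymphatic gene. Without the 5 libraries with Glycam1 and Chst4 reads 22 cell division and 11 endothelial genes passed. That fit held only WDLPS 2 and 3 against Normal Fat 2 and 3, with WDLPS 3 at 0 counts for 5334 of the genes tested in the full set.

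Camera passed 15 of the 37 lists in WDLPS against Normal Fat. The 8 higher were macrophage (adjusted p = 6.05e-08), collagen and matrix (3.12e-06), proteases (3.12e-06), cytokines (1.02e-05), hypoxia (4.31e-05), monocyte and neutrophil (0.00058), cell division (0.00107) and interferon (0.0041, median 0.70). The 7 lower were endothelial (0.000968, median -0.78), T cell (0.00194), B cell (0.00796), lymph node stroma (0.0175), lipogenesis (0.0175, median -0.87), mast cell (0.029, median -0.92) and regulatory T cell (0.046, median -2.22). The smallest was adjusted p = 0.415 with an estimated correlation, and fry passed 0 lists by either p. Without WDLPS 2 camera passed 7 lists, and cell division moved to the lower side (median -0.60, adjusted p = 0.856). With the B cell and skeletal muscle covariates T cell genes moved to the higher side (median -0.10) and did not pass. Of those not passed, the medians were 0.32 for p53 targets, -0.24 for FOXO targets, 0.34 for oxidative phosphorylation, 0.22 for progenitors, -1.06 for smooth muscle and pericytes and -0.51 for lymphatic endothelium. They were 0.48 for plasma cells, -1.0 for dendritic cells, -0.78 for checkpoints, 0.05 for MHC class I, -1.12 for MHC class II, -0.77 for skeletal muscle and 0.51 for mammary epithelium. Skin genes had 0.43, nerve genes -0.52, erythroid genes -0.11, and bone and cartilage genes 0.65, or 0.15 with members at 0 in a group put at their limit. Camera put cytotoxic and NK cell genes (median -0.38, mean -0.13) and amplicon orthologs (median 0.09, mean -0.22) on the higher side.

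Over all genes edgeR called 0 genes between WDLPS and Normal Fat, with a smallest adjusted p of 0.452, while 1257 genes had an unadjusted p under 0.05 and DESeq2 called 136. The groups did not overlap for 1670 genes, 8.87% against 5.71% by chance.

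The third comparison asked what sets DDLPS apart from WDLPS within the same model. A minority of matrix and chemokine genes and 5 of 7 erythroid genes passed over the list alone, in numbers that changed with the libraries kept, so no direction is drawn for these lists as a whole. Tnc had 2647 ± 2692 CPM in DDLPS and 9.25 ± 1.81 in WDLPS, Bgn 3242 ± 2070 and 251 ± 106, and Col12a1 779.8 ± 879 and 18.2 ± 15.7. They, Col11a1 and Thbs2, the last named after its values were seen, were higher in DDLPS over the list alone, as 5 of 22 matrix genes at a median of 2.08. The number was 11 without DDLPS 3, 2 without WDLPS 1 and 0 without WDLPS 3. The chemokines Ccl8 (37.4 ± 27.0 in DDLPS against 327 ± 144 CPM, no overlap), Ccl6 and the eosinophil attractant Ccl11 were lower in DDLPS over the list alone and Il1b higher, as 4 of 28 cytokine genes. Their list median was 0.57 and mean 0.16, with camera on the lower side, and the number was 8 without DDLPS 3 and 2 without WDLPS 2. Hba-a2 had 86.3 ± 60.5 CPM in DDLPS and 631 ± 689.9 in WDLPS, and 5 of 7 erythroid genes (with Hba-a1, Hbb-bt, Hbb-bs and Alas2, the last named after its values were seen) were lower over the list alone, at a median of -2.53, and 0 without WDLPS 1 or 3. Among progenitor genes Pdgfrb was higher and Ly6a (204 ± 145 against 703 ± 279.5 CPM), Cd34 and Gsn lower, at a median of -0.55. The number was 1 without DDLPS 1, 2 or 4, 2 without DDLPS 5 and 0 without WDLPS 2. Within the AS libraries, with 2 WDLPS, 1 matrix, 3 cytokine, 6 progenitor and 0 erythroid genes passed over the list alone. Without the 4 muscle-rich libraries 1 matrix and 2 erythroid genes passed, without the 5 libraries with Glycam1 and Chst4 reads 9 cytokine, 2 progenitor and 0 erythroid genes, and with only the 2 groups fitted 0 progenitor genes.

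Further genes passed over the list alone between DDLPS and WDLPS in the full set, and none of their lists kept its count through every removal, so no direction is drawn. They were Runx2 and Acan (list count 1 without DDLPS 4, 5, 6, 7, 9 or 10 or WDLPS 2 or 3), and Prdm1 and Xbp1 (list count 1 without DDLPS 5, DDLPS 9 or WDLPS 2, 0 without WDLPS 1 or 3). For Il1b, Mmp9, Retnlg and Clec4d the list count was 0 without DDLPS 4, 6 or 7, WDLPS 2 or 3 or Normal Fat 4, 1 without DDLPS 9 or 10 and 2 without DDLPS 8, WDLPS 1 or Normal Fat 2. For Egr3 and Klf4 it was 4 without DDLPS 3, 1 without WDLPS 3 and 2 without DDLPS 8, WDLPS 2 or Normal Fat 1, and 0 otherwise. For Pmp22 and S100b it was 0 without DDLPS 1, 4, 5, 6 or 9 or WDLPS 2 or 3, 1 without DDLPS 2, 7 or 10, WDLPS 1 or Normal Fat 2, 3 or 4, 3 without DDLPS 3 and 2 otherwise. Fscn1 was lost without DDLPS 3, 4 or 6, any WDLPS library or Normal Fat 4, and Hdc without DDLPS 1, 2, 4, 5 or 7 or WDLPS 1 or 3. For Dcxr the p53 target list gave 0 genes without DDLPS 2, 4, 5, 7, 8, 9 or 10, WDLPS 1 or 3 or Normal Fat 3 or 4, 2 without DDLPS 1 or 3 and 4 without WDLPS 2. For Ebf2 the brown and beige fat list gave 0 without DDLPS 4 or WDLPS 2 and 2 without WDLPS 1 or 3.

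Fat cell, cell division and macrophage genes did not pass singly between DDLPS and WDLPS. No adipocyte gene passed, Fabp4, a fatty acid carrier, having 605 ± 1188 CPM in DDLPS and 11552 ± 12073 in WDLPS, at a list median of -2.97, and no cell division gene, Mcm3 having 83.9 ± 30.8 and 26.0 ± 17.8, at 1.94. No macrophage gene passed, at a median of -0.36, Trem2 having 29.0 ± 16.5 CPM in DDLPS and 124 ± 102 in WDLPS. Over the list alone 18 adipocyte genes were lower in DDLPS without DDLPS 3, 11 without DDLPS 8 and 2 without WDLPS 2. Cell division genes were higher, 19 without WDLPS 2, 15 without DDLPS 3 and 11 without Normal Fat 1. With the B cell and skeletal muscle covariates 22 adipocyte and 18 cell division genes passed. Macrophage genes were lower, 4 without DDLPS 8, 3 without DDLPS 3, 2 without Normal Fat 1 and 1 without DDLPS 7, WDLPS 1 or WDLPS 3. Removal of DDLPS 3 also gave 12 mammary, 9 skin and 3 lipogenesis genes lower and 2 protease genes higher, that of DDLPS 1 10 oxidative phosphorylation genes lower, and that of WDLPS 1 9 endothelial, 4 lymphatic and 4 smooth muscle and pericyte genes higher. In the other lists with no gene past, a removal gave at most 2 genes, namely of DDLPS 1 (hypoxia), DDLPS 3 (FOXO, cytotoxic and NK cell, smooth muscle), DDLPS 8 (cytotoxic and NK cell, lipogenesis), WDLPS 2 (lipogenesis) and WDLPS 3 (skin).

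Camera passed 9 lists between DDLPS and WDLPS. Cell division (adjusted p = 8.83e-10) and matrix (0.000288) were higher in DDLPS, and adipocyte (4.22e-12), erythroid (0.00155), mammary (0.00188, median -2.41), skin (0.00188, median -2.34), oxidative phosphorylation (0.00257, median -0.53), nerve (0.00664, median -1.16) and macrophage (0.0391) lower. Oxidative phosphorylation moved to the higher side without WDLPS 3 (median 0.20) and within the AS libraries (0.19), so its direction rests on that library. Without DDLPS 8 camera passed 15. All 9 had adjusted p = 0.920 with an estimated correlation, and fry passed 0 lists by its directional p and 4 by its mixed p. WDLPS 1 was rich in mammary genes. Lists that did not pass had medians of 2.77 for T cells, 1.62 for regulatory T cells, 2.29 for B cells, 2.59 for lymph node stroma, 1.07 for checkpoints, 0.81 for MHC class II and 0.90 for dendritic cells, with DDLPS 2 and 3 rich in lymphocyte genes. They were -0.33 for MHC class I, -0.37 for interferon, 0.42 for monocytes and neutrophils, -0.13 for plasma cells, -1.07 for mast cells, 1.13 for proteases, -0.11 for hypoxia, -0.60 for lipogenesis and -1.09 for brown and beige fat. Medians were 0.28 for endothelium, 0.67 for lymphatic endothelium, 1.02 for smooth muscle and pericytes, 0.66 for bone and cartilage, 0.18 for amplicon orthologs and 0.70 for the immediate early list. Camera put the p53 target (median 0.01, mean -0.13), FOXO target (0.01, -0.02), cytotoxic and NK cell (0.07, -0.28) and skeletal muscle lists (2.14, 2.39) on the lower side.

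Over all genes edgeR called 1 gene between DDLPS and WDLPS, Blvrb (ENSMUSG00000040466), a biliverdin reductase of heme breakdown. It had 25.8 ± 10.6 CPM in DDLPS and 114 ± 76.9 in WDLPS, and was lower in DDLPS by -1.99 log2 (SE 0.28, adjusted p = 0.0404). The call stood only without DDLPS 3 or DDLPS 8 among the 17 removals, whose adjusted p-values ran from 0.00682 to 0.218, and without these 2 libraries edgeR called 784 and 110 genes. Removing WDLPS 2 left 1 gene called and removing any other library 0. At an unadjusted p under 0.05 there were 3869 genes, 2015 higher and 1854 lower, DESeq2 called 2080, and edgeR called 13 within the AS libraries. Groups did not overlap for 321 genes, 1.71% against 0.699% by chance.

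The series title concerns the heterogeneity of the immune microenvironment, so the spread of immune genes was measured among the 10 DDLPS tumors. Mean log2 CPM of T cell genes had an SD of 2.58 and a range of 7.44, with DDLPS 2 and 3 at 5.43 and 6.96 and the other 8 tumors between -0.48 and 1.48. Without that pair the SD was 0.64 and the range 1.96. B cell genes had an SD of 2.98 and plasma cell genes 2.58, and 0.43 and 0.61 without that pair. In Normal Fat the SD was 3.69 for T cell, 3.89 for B cell and 1.63 for plasma cell genes, and in WDLPS 2.14, 2.68 and 3.46. Wide spread of T cell and B cell genes was thus not particular to DDLPS. DDLPS 3 also had a mean Spearman correlation of 0.910 with Normal Fat. Among all 10 tumors the SD was 1.49 for regulatory T cells, 1.47 for cytotoxic and NK cells, 1.75 for MHC class II, 1.37 for checkpoints and 1.21 for dendritic cells. Without DDLPS 2 and 3 these were 0.41, 1.01, 0.72, 0.42 and 0.69. Macrophage genes had an SD of 0.61 and a range of 2.10, monocyte and neutrophil genes an SD of 0.66, cytokines 0.54, interferon genes 0.91, MHC class I genes 1.01 and mast cell genes 1.46. Without DDLPS 2 and 3 these SDs were 0.61, 0.54, 0.41, 0.91, 0.85 and 1.45. Within the 7 AS tumors the SD was 2.88 for T cell and 0.49 for macrophage genes.

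Correlations with the T cell score were computed only within the 8 DDLPS tumors of lower score, since the tumors fell into 2 clusters separated by 3.95 log2. None of 9 relations passed Benjamini-Hochberg adjustment of two-sided exact permutation tests. Interferon genes gave Pearson r = 0.75 (exact p = 0.0330, adjusted p = 0.198) and Spearman rho = 0.71 (exact p = 0.0576). MHC class I genes gave r = 0.73 (exact p = 0.0439, adjusted p = 0.198) and rho = 0.69 (exact p = 0.0694). Without DDLPS 4 and 9, the farthest from the median T cell score, r was 0.80 (exact p = 0.0556) for interferon and 0.59 (exact p = 0.215) for MHC class I genes. Centred within title series, r was 0.86 and 0.85, with permutation p-values of 0.0167 and 0.0125 that are not adjusted over the 9 relations. The 5 AS and 3 R tumors of that cluster were too few for separate values. Pearson r with T cell genes was 0.64 for checkpoints, 0.45 for MHC class II, 0.43 for B cells, 0.43 for adipocytes, 0.10 for macrophages, 0.05 for cell division and 0.04 for matrix genes, with exact adjusted p-values of 0.257 to 0.929. Without DDLPS 4 and 9 these values also moved, to -0.88 (exact p = 0.0389, unadjusted) for matrix genes, -0.65 (exact p = 0.157) for cell division, 0.42 for checkpoints and 0.047 for MHC class II, so no direction is drawn for them.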

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

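The tests of whether DDLPS 3 is a mislabelled Normal Fat library and of high endothelial venule genes in 4 libraries, and the fits without sets of libraries or with covariates, were chosen only after the result was seen.

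Among 90 values examined for a library far from the rest of its group, 8 had one, where chance gives about 1 in 20, or 4.5. The measure is the gap to the nearest other library as a share of the group's range. Of the 8, 5 were in DDLPS 3. Its matrix score was 5.62 against 9.38 in the nearest DDLPS (ratio 0.605), its protease score 2.80 against 5.59 (0.640), its mammary score 6.80 against 1.27 (0.611), its skin score 2.44 against -0.51 (0.560) and its Cdkn2a 2.80 against 7.23 log2 CPM (0.723). DDLPS 1 had an oxidative phosphorylation score of 8.90 against 7.21 (0.659), and skeletal muscle genes in the same library averaged 13.09. DDLPS 8 had a progenitor and fibroblast score of 7.30 against 6.06 (0.579). The mast cell score of Normal Fat 1 was 1.28 against 2.37 in the nearest Normal Fat library (0.878). No explanation was tested for these last 3.

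Transgene sequences in the tables, which no comparison used, gave a signal in tumors. Cre reads occurred in 9 of 13 tumor libraries, with up to 68 counts, and in 0 of 4 Normal Fat libraries (two-sided Fisher exact p = 0.0294). Reads of eGFP occurred in 6 of 13 tumor libraries and 0 of 4 Normal Fat libraries (two-sided Fisher exact p = 0.237). No explanation was tested for either.

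The first pattern weighed is that DDLPS 3 lay with Normal Fat, at a mean Spearman correlation of 0.910 with Normal Fat and 0.811 with the other DDLPS. Its 5 Cre reads had a binomial probability of 0.000344 given 0 in the 4 Normal Fat libraries, which argues against a mislabelled Normal Fat library as far as counting error goes and leaves open uneven carry-over from libraries with up to 68 Cre reads. Mostly non-tumor tissue with a minority of tumor cells may remain: of 11 genes at 10 CPM or more in the mean of the other 9 DDLPS and at most 0.2 CPM in every Normal Fat library, 4, or 36.4% (95% Wilson interval 15.2 to 64.6), exceeded the highest Normal Fat library, where chance gives 20%. That share cannot be told apart from chance with 11 genes, whose median level in DDLPS 3 was 0.102% of the mean of the other 9, with Chil4 at 0 against 315 CPM. No biological explanation was tested, since the design names none within DDLPS.

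The second pattern is that lymphocyte genes were high in 5 libraries of all 3 groups. Lymph node tissue in the collected piece is a candidate explanation for 4 of them, Normal Fat 1 and 4, WDLPS 1 and DDLPS 3. All 4 had reads of both Glycam1 and Chst4, and none of the 12 libraries outside the 5 had both, although Glycam1 is also a milk protein gene and 3 of the 4 held mammary epithelium genes. For DDLPS 2 lymph node tissue and lymphocytes in the tumor cannot be told apart, since its ratio of Glycam1 and Chst4 to T and B cell CPM was 0.00514, below Normal Fat 1 (0.0181) and Normal Fat 4 (0.142) and near WDLPS 1 (0.00729). DDLPS 2 also had reads of both genes, so these do not set WDLPS 1 apart from it. WDLPS 1 had 139 T cell CPM against 3588 B cell CPM, and DDLPS 2 982 against 2610. The same uncertainty therefore holds for WDLPS 1. No biological explanation was tested.

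The third pattern is the low count of genes between DDLPS and Normal Fat, 1 by edgeR against 3934 with an unadjusted p under 0.05. A wider spread from DDLPS 3 is a candidate explanation, since without it edgeR called 2151 genes. For lymphoid and muscle content, the count was again 1 with B cell and skeletal muscle scores as covariates and 0 without the 4 muscle-rich libraries. By the rule set before the covariate fit, its count of 1 counts against this explanation. Both fits leave fewer residual degrees of freedom. That alone does not prevent calls, since with the same covariates the count between DDLPS and WDLPS was 918, against 1 without them. The fit without the 4 libraries cannot decide, since 0 also followed removal of the muscle-rich Normal Fat 3 alone. A part of lymphoid and muscle content in the low count stays open. The count was 499 without the muscle-rich DDLPS 8, 355 without the lymphocyte-rich Normal Fat 1 and 281 without WDLPS 1. It was 1246 without the 5 libraries with Glycam1 and Chst4 reads, which include DDLPS 3, but 0 without DDLPS 2 or Normal Fat 3. No biological explanation was tested.

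Other splits of the libraries were compared with the real one. Between DDLPS and Normal Fat, 1 of 60 splits, the real one, gave as many genes with an unadjusted p under 0.05 (3934, highest other 2738). By DESeq2 1 of 40 gave as many (2429, highest other 1169). Both shares were under 0.05 among the splits drawn. Many of those splits put R libraries in the smaller group, while the real Normal Fat group holds only AS libraries and the fit carries title series. Such splits are not equivalent to the real one, so these shares do not exclude chance. By edgeR 2 of 60 gave as many as the real 1 gene (highest other 1), a count too low to exclude chance. Between WDLPS and Normal Fat, 7 of 35 splits gave at least the 1257 genes with an unadjusted p under 0.05 (highest other 2449), so chance cannot be excluded, and the real count of 0 by edgeR (highest other 1), which all 35 splits reach by construction, tests nothing. Between DDLPS and WDLPS, 14 of 60 splits gave at least the real 1 gene (highest other 3910) and 5 of 60 at least 3869 with an unadjusted p under 0.05 (highest other 6796), so chance cannot be excluded. The split with the highest counts set DDLPS 8, 9 and 10, all of title series R, against the rest, where WDLPS 3 was the only R library. The fit of that split held title series as a term, so its count is what remained after that term. The term there rested on WDLPS 3, which had 0 counts for 5334 of the tested genes. With the real groups, edgeR called 13 genes within the AS libraries.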

How the results depend on the processing

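The adjusted p under 0.1, robust dispersions, limma-voom, the fits without DDLPS 3 and WDLPS 3, without the 4 muscle-rich libraries or without the 5 libraries with high endothelial venule reads, and the covariates were chosen after the data were seen. The correlations within AS tumors of the lower cluster were not run, since 5 are too few. Between DDLPS and Normal Fat, where edgeR called 1 gene, it called 1448 at an adjusted p under 0.1, 3 with RLE or upper-quartile normalization, 99 at 50 counts or more in 3 samples, 122 with no title series term, 0 with AS libraries only, 502 with only the 2 groups, 0 in a test against a fold change of 2, 3033 without DDLPS 3 and WDLPS 3, 0 without the muscle-rich libraries and 1246 without those with high endothelial venule reads. DESeq2 called 2429 and limma-voom 7498, and leaving out 1 library gave 0 to 2151. EdgeR again called 1 with no filter, with robust dispersions and with the covariates. Between WDLPS and Normal Fat, where edgeR called 0 and 1257 genes had an unadjusted p under 0.05, DESeq2 called 136, the fit without high endothelial venule reads 27, that with covariates 1 and limma-voom 0, and each removal of 1 library 0. The fit without high endothelial venule reads held only WDLPS 2 and 3 against Normal Fat 2 and 3. Between DDLPS and WDLPS, where edgeR called 1 gene, it called 0 with no filter, with no title series term, with only the 2 groups, against a fold change of 2 and without DDLPS 3 and WDLPS 3, 13 with AS libraries only, 6 and 3 without the muscle-rich libraries and those with high endothelial venule reads, and 918 with the covariates. DESeq2 called 2080 and limma-voom 783, and leaving out 1 library gave 0 to 784. Lists past camera numbered 17, 15 and 9 in the 3 comparisons, 0, 0 and 0 with an estimated correlation, 9, 0 and 0 by fry, and 15 to 21, 7 to 20 and 8 to 15 with 1 library left out. Over all genes, Trp53 passed between DDLPS and Normal Fat at -1.12 by limma-voom. Camera's direction reversed for oxidative phosphorylation between DDLPS and WDLPS (median 0.19 with AS libraries only, 0.20 without WDLPS 3, 0.23 without DDLPS 3 and WDLPS 3, and -1.01 to 0.20 over removals of 1 library), and between WDLPS and Normal Fat for cell division without WDLPS 2 (-0.60, with medians of -0.60 to 1.64 over removals of 1 library), mammary genes without the muscle-rich libraries (-0.43) and without high endothelial venule reads (-5.18). Without those reads it also reversed in that comparison for T cells (-0.28), plasma cells (-2.29) and checkpoints (1.08). With the covariates it reversed for T cells (-0.10) there, and for T cells (0.83) and checkpoints (0.63) between DDLPS and Normal Fat. Of 2769 list calls under other settings 2480 were the same, 118 newly past the threshold, 159 no longer past it and 12 reversed, the B cell and skeletal muscle lists having no value with their own scores as covariates. The range of list scores among DDLPS moved with the median of members for regulatory T cells (6.96), macrophages (2.95), mast cells (6.48), checkpoints (5.75), MHC class II (3.34) and cytokines (2.85), and with AS libraries only for macrophages (1.39) and dendritic cells (2.90). Fewer libraries were fitted in the settings that leave libraries out, and for the other changes the cause was not tested. On simulated counts edgeR recovered 0% of genes changed by 1 log2 between DDLPS and Normal Fat, which limits small changes at this spread and depth.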

Other observations

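The first 2 principal components of log2 CPM over the 17 libraries held 31.8% and 21.9% of the variance. Normal Fat 2 had 1 read of Xist, the transcript of the inactive X chromosome, and 0 reads of each of the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty, and WDLPS 3 had 31 reads of Xist and 0 of those 4. Each of the other 15 libraries had at least 3128 reads of Xist or at least 884 of Ddx3y. Those with Ddx3y at that level were Normal Fat 1 and 3, WDLPS 2 and DDLPS 1, 5 and 6. Those with Xist were Normal Fat 4, WDLPS 1 and DDLPS 2, 3, 4, 7, 8, 9 and 10. No fit held sex as a term. The DDLPS tumor with the most counts in few genes was DDLPS 1, whose 50 highest genes held 41.2% of its counts and whose mitochondrial genes held 12.3%.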
